A study of Mus musculus with 2 samples.

How the data were processed

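The study measured polyadenylated RNA in adult mouse thymus, in 2 libraries of 1 group, each labelled as the thymus of an individual male mouse and both with the same donor label. The labels name them biological replicates 1 and 2. The authors deposited 1 table of genes and 1 table of transcripts per library, made against assembly mm10 per the labels and GENCODE release M4 per the deposited listing of files. The quantification program and its version are not given in the sources used here. The labels also refer to a set of spike-ins.

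Per the file headers, the deposited tables hold expected counts, which need not be whole and carry no scaling for depth. They also hold, per the file headers, TPM and FPKM as maximum likelihood values, posterior mean estimates of the count and of TPM, a posterior standard deviation of the count, and the percent of each gene's expression on each transcript. The deposited percent columns were not used. Length minus effective length was 35 nt in 99.95% of rows. Besides 43346 mouse gene identifiers, the tables list 26248 rows named by a bare number (median length 73 nt), 96 rows of ERCC spike-ins and 1 row of phiX174. What the numbered rows are is not given in the sources used here. The numbered rows and phiX174 share the total of the authors' TPM, which lowers the TPM of mouse genes by an amount that differs between the libraries, while the ERCC rows held 0 counts. These 3 kinds of row were left out of mouse totals, tests and gene lists.

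Identifiers were matched without version to GENCODE M21 (assembly GRCm38, the same assembly as mm10), which gave names, types and coordinates for 42462 of the identifiers, and 884 stayed unnamed. Coordinates are those of M21 and 1-based. Reads of a gene and its copies or of overlapping genes can be divided between them, and the strand setting of the counting is not given in the sources used here.

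Levels are the mean and SD of TPM over the 2 libraries (n = 2), which measures the spread of these libraries only. A gene was called detected at a TPM of 1 or more in both. The 30 gene lists were fixed before the data were examined and hold 466 members, of which 5 had no match (Trdc, Faslg, Iglc1, Hbb-b1 and Hbb-b2). A list's median mean TPM, over all matched members, was ranked among 10000 random lists of equal size from genes detected in either library. Its median log2 ratio of TPM + 1 (replicate 2 over replicate 1) was ranked among 10000 random lists matched on deciles of mean expression. Ratios on that scale understate changes of low genes. Summed expected counts per 10000 mouse counts were added after the data were seen, with exact Poisson intervals of 95% and an exact binomial test between the libraries. Shares within a locus carry Clopper-Pearson intervals, and a two-sided Fisher's exact test of each segment with counts, on rounded counts in loci with counts in both libraries, was added after the data were seen. The count tests used rounded counts, and the genes without counts in 1 library were taken before rounding. These intervals, and the floor of 3 counts, cover counting error only, since reads without molecular identifiers are not independent molecules. Intervals from 10000 draws of a set's genes with replacement, added after the data were seen, also cover the spread between genes.

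Expected counts were rounded to whole numbers for edgeR 4.0.16 and DESeq2 1.42.0 (R 4.3.3). The planned analysis used edgeR with TMM scaling and filterByExpr, an intercept-only fit for the coefficient of variation and a two-sided exact binomial test per gene with Benjamini-Hochberg adjustment at 0.05. The libraries were treated as 2 replicates per the labels. A chi-square of 2634 on 353 degrees of freedom over the filtered genes does not say whether they come from separate animals. With 1 group there was no test between conditions. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

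The named genes were chosen by a rule fixed before the data were examined. It takes the 20 of highest mean TPM outside mitochondrial and spike-in rows, of which 3 turned out to be numbered rows. It takes up to 6 detected members of each list by mean TPM, landmark genes, and every member of the sex-linked, strain-linked and shortest lists. It takes the 10 largest ratios in each direction among genes with a mean TPM of 10 and a mean count of 50 or more, which 26 genes met. It takes the 5 top segments per receptor locus, and genes by their dominant transcript. Genes named outside it (mt-Atp6, mt-Nd4, Stx4a, Galnt13, Thg1l, Exoc8, Gm26917 and Srrm2) were chosen after their values were seen.

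The procedures were tested on simulated data. For the comparison of replicate 2 with replicate 1, 200 genes were changed in counts simulated with counting error only. The binomial test called 21.8% of genes changed 2-fold, 89.9% of those changed 4-fold and 96.2% of those changed 8-fold. The real libraries differed beyond counting error, so these shares need not hold for them. The coefficient of variation was recovered as 0.146, 0.286 and 0.393 under filterByExpr where 0.2, 0.4 and 0.6 were set, and as 0.194, 0.401 and 0.59 with a mean count of 10 or more. Of simulated lists of 15 genes, 5.5% fell outside the central 95% without a shift, 45% with a log2 shift of 2 and 95.5% with a log2 shift of 4.

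Alternatives covered FPKM, posterior means, TPM rescaled without mitochondrial, ribosomal RNA and spike-in rows, other thresholds, pseudocounts, scalings and filters, and each library alone. Added after the data were seen were the filter on a mean count of 10 or more, ranking by expected count, and the ratio of summed counts with and without the most abundant rows.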

Results

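Gene expression was measured by sequencing of polyadenylated RNA in the thymus of adult male B6NCrl mice of 8 weeks. The thymus is the organ in which T cell precursors (thymocytes) rearrange their antigen receptor genes and are selected by epithelial cells. The series held 1 group, adult thymus, with 2 libraries named replicate 1 and replicate 2. Each was described as the thymus of an individual mouse, although both carried the same donor label. No treatment, age or tissue was contrasted, so the question the design allows is which genes adult thymus expressed, at what level, and how far the 2 libraries differed. The tables held few reads, and whether they cover all reads of each library is not given in the sources used here, so limits on detection hold for these tables. The expected counts summed to 76275.95 in replicate 1 and 72004.56 in replicate 2. Mouse genes held 41339.12 and 47147.66 of these, and the row of the bacteriophage phiX174 held 34766 and 24714. In replicate 1, 3388 genes stood at a single count, worth a median TPM (relative abundance scaled for length) of 10.6. In replicate 2, 3182 genes did, at a median of 10.4 TPM. Levels of single genes are therefore given with their counts. A count of 0 allows up to 3 counts, equal to 0.726 per 10000 mouse counts in replicate 1 and 0.636 in replicate 2.

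Genes of double-positive thymocytes, the cortical stage that carries both CD4 and CD8, were the most abundant of the cell type lists. The 18 genes of this list summed to 576 expected counts in replicate 1 and 551.7 in replicate 2, or 128 ± 15.8 per 10000 mouse counts (SD, n = 2). Of its members, 16 reached a TPM of 1 in both libraries, and the median mean TPM of all 18, 262, lay above all 10000 random lists of detected genes. The median was 291 TPM in replicate 1 and 174 TPM in replicate 2, and 14 in the posterior mean TPM, which gives a prior amount to every row without reads. Rag1, which encodes a subunit of the recombinase that cuts antigen receptor genes, had 155 and 133 counts and a TPM of 513 ± 71 (SD, n = 2). Its partner Rag2 had 13 and 6 counts (98 ± 53 TPM). The coreceptor genes stood at 60 and 48 counts for Cd4 (499 ± 102 TPM), 47 and 39 for Cd8a (328 ± 54 TPM) and 34 and 35 for Cd8b1 (583 ± 6.36 TPM). Dntt, the polymerase that adds untemplated nucleotides to receptor joints, had 29 and 51 counts (456 ± 163 TPM). Arpp21 had 39 and 53 counts, and Rorc, a nuclear receptor of this stage, 12 and 8. Ptcra, which encodes the surrogate chain of the pre-T cell receptor, had 0 counts in both libraries and was not detectable at this depth. Rag1 lies on chromosome 2 (101638282 to 101649501, mm10), Cd4 on chromosome 6 (124864692 to 124888221), and Cd8a (71373427 to 71379173) and Cd8b1 (71322788 to 71337494) lie beside each other on chromosome 6. All 4 are annotated as protein-coding genes.

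The receptor and its signalling genes all reached the detection level, some of them on few counts. Trac had 2 and 1 counts, Zap70 4 and 3, and Fyn 4 and 4. All 22 members of the list of T cell receptor complex and signalling genes reached a TPM of 1 in both libraries, with a median of 221 TPM, above all random lists, and 86.8 ± 10.2 counts per 10000 mouse counts (SD, n = 2). Lck, the kinase bound to the coreceptors, had 42 and 29 counts, and the surface glycoprotein gene Thy1 had 65 and 30. The 2 constant-region genes of the beta chain, Trbc1 with 14.6 and 42 counts and Trbc2 with 24.4 and 55, are near-identical copies, so the division of reads between them is uncertain. Their sum of 39 and 97 counts was 2.18 times as large a share in replicate 2 (exact 95% interval 1.49 to 3.25). The 19 transcription factors of the T lineage were likewise all detected, with a median of 96.7 TPM and 99.8 ± 9.78 counts per 10000 (SD, n = 2). Tcf7, an effector of Wnt signalling needed for T lineage commitment, had 131 and 87 counts (1203 ± 232 TPM). It lies on chromosome 11 (52252371 to 52283014). Satb1, a chromatin organiser on chromosome 17 (51736187 to 51833290), had 87.8 and 118 counts (580 ± 104 TPM). Ets1 had 38 and 55 counts, and Lef1 27 and 15. Other factors of this list rested on few counts, such as Runx3 with 2 and 1 and Id2 with 1 and 2.

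**Figure D1:**
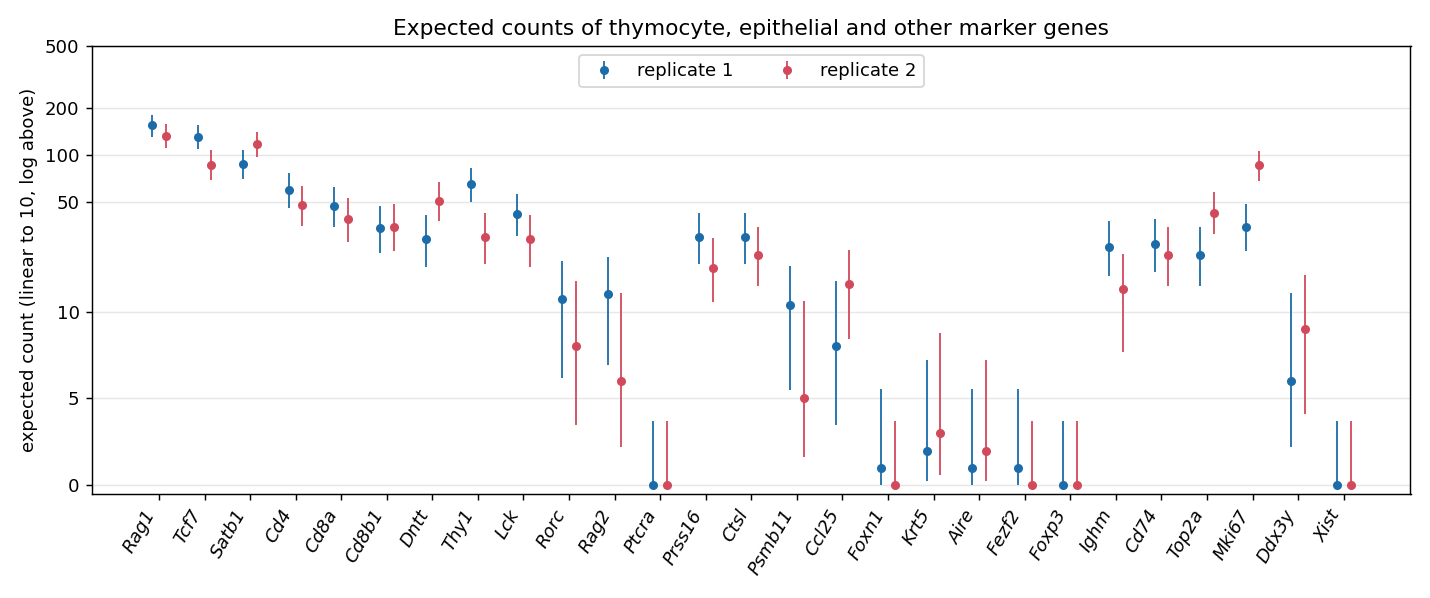
Expected counts of marker genes in the libraries of replicate 1 and replicate 2 (vertical axis linear up to 10 and logarithmic above). Points are the counts and bars their exact Poisson 95% intervals, which cover counting error only. Rag1 stood at 155 and 133 counts, while Ptcra, Foxp3 and Xist stood at 0 in both libraries.

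Lists of earlier and later thymocyte stages lay far lower. Of 16 genes of double-negative cells and early T progenitors, 6 were detected in both libraries, and the list summed to 15 and 18 counts. Il2ra, an interleukin 2 receptor chain of double-negative cells, had 4 counts and 1, and Cd44 had 3 and 6. Of 14 genes induced by positive selection, 10 were detected, with 12.6 ± 1.3 counts per 10000 (SD, n = 2); Rasgrp1, an activator of Ras, had 24 and 27 counts and Cd5 10 and 2. Of 13 genes of mature single-positive cells and thymic egress, 8 were detected, with 27.5 and 34 counts. Among them Cd52 had 11 and 5 counts, Sell (L-selectin) 3 and 13, and Ccr7 1 and 4. Of 12 regulatory T cell genes, 2 were detected in both libraries. Foxp3, the master regulator of that lineage, had 0 counts in both, and Ikzf2 had 2 and 11. The regulatory T cell list summed to 4 and 16 counts. The list of gamma-delta and innate-like T cells summed to 9.99 and 3 counts, with 3 of 14 members detected in both.

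Thymic epithelium was represented mainly by cortical genes. Of 12 genes of cortical epithelium, 9 were detected in both libraries. The median of all 12 was 61.3 TPM, at percentile 99.6 of random lists, and the 12 summed to 108 and 103 counts, or 24 ± 3.03 per 10000 (SD, n = 2). The proteases of peptide presentation led this list. Prss16, thymus-specific serine protease on chromosome 13 (22002173 to 22009742), had 30 and 19 counts (544 ± 50 TPM), and Ctsl, cathepsin L, 30 and 23 (321 ± 70 TPM). Psmb11, the thymoproteasome subunit, had 11 and 5 counts, and the chemokine gene Ccl25 had 8 and 15. Foxn1, the transcription factor of thymic epithelium, had 1 count in replicate 1 and 0 in replicate 2. The 14 medullary genes held fewer counts. They summed to 16.4 and 18.1 counts, with 5 members detected in both libraries and 5 at 0 counts in both. The median of all 14 was 4.75 TPM, at percentile 0.01 of random lists. Random lists hold only genes detected in either library, so a list with members at 0 counts ranks low by construction. This percentile therefore says little about the level of medullary genes. That median was 0 in replicate 1 and 6.51 TPM in replicate 2. Aire, which drives expression of tissue-restricted antigens in the medulla, had 1 and 2 counts, Fezf2 had 1 and 0, and Krt5 2 and 3. Ccl21a, with 9.4 and 5.03 counts, is one of several similar gene copies. Among 40 tissue-restricted antigens, 27 had 0 counts in both libraries and 4 were detected in both: Mbp, Plp1, Gad1 and Apob, each with 4 counts or fewer per library.

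Other cell types contributed few counts. The B and plasma cell list summed to 44 and 38 counts, of which Ighm, the heavy chain constant region of IgM, held 26 and 14. The list of class II antigen presentation summed to 70 and 60, with Cd74 at 27 and 23 and H2-Ab1 at 16 and 6, although only 4 of its 12 members reached a TPM of 1 in both libraries. Dendritic cell genes summed to 18 and 16 counts and macrophage and granulocyte genes to 36 and 18. Mesenchymal genes summed to 28.1 and 20 counts, endothelial genes to 7 and 9.94, adipose genes to 7 and 15, and erythroid and platelet genes to 3 and 8. Hba-a2, a hemoglobin chain, had 1.82 and 4 counts. None of the 4 parathyroid genes (Pth, Gcm2, Casr and Chga) and none of the 18 genes of striated and cardiac muscle had a count in either library. Each of these 2 lists is limited to 0.726 and 0.636 per 10000 mouse counts by the floor of 3 counts per library.

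**Figure D2:**
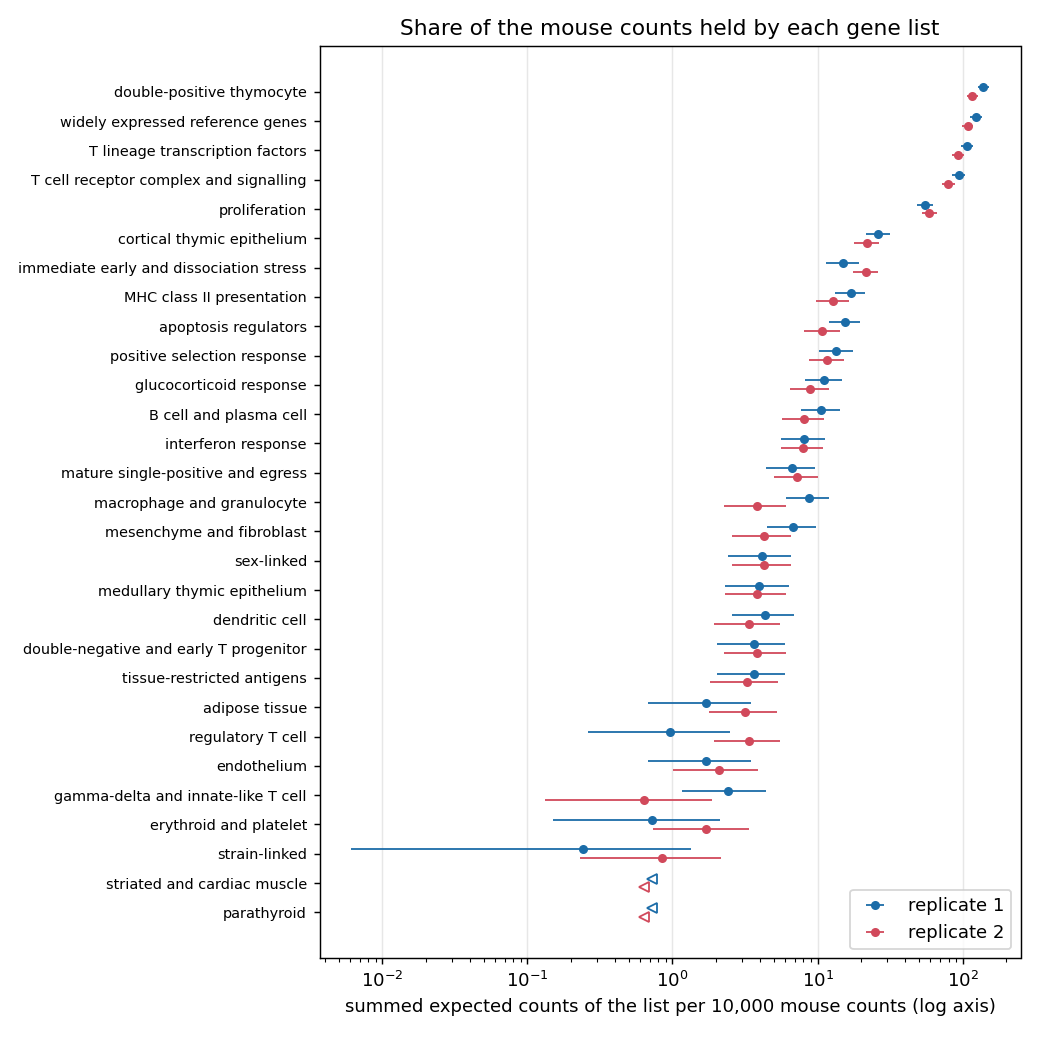
Summed expected counts of 29 gene lists per 10000 mouse counts (horizontal log axis) in replicate 1 and replicate 2. The mitochondrial list is left out. Points are the sums and bars exact Poisson 95% intervals; open triangles mark lists at 0 counts, placed at the limit that 0 counts allows (0.726 and 0.636). Double-positive genes stood highest, at a mean of 128.

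Genes of cell division were well represented. Of 26 proliferation genes, 23 were detected in both libraries. The median of all 26 was 67.8 TPM, above all random lists, and the list held 57.1 ± 2.7 counts per 10000 (SD, n = 2). Mki67, a nuclear protein of cycling cells, had 35 and 86 counts, Top2a (topoisomerase II) 23 and 43, and Tubb5 66 and 28.5. Of 17 apoptosis regulators, 13 were detected, with 64 and 50.9 counts, led by Bcl2l1 (10 and 6) and Mcl1 (10 and 10). Of 13 genes of the glucocorticoid response, 7 were detected, with 46 and 42 counts; the receptor gene Nr3c1 had 13 and 10, and Fkbp5 had 16 and 17. Of 18 interferon response genes, 8 were detected, with 33.4 and 37.3 counts. The list of immediate early and dissociation stress genes summed to 61.8 and 102 counts, with 7 of 16 members detected in both. The heat shock genes Hspa8 (23.3 and 57.7 counts) and Hsp90aa1 (15.5 and 26.8) held most of them. The 14 widely expressed reference genes were all detected, at a median of 378 TPM and 116 ± 11 counts per 10000 (SD, n = 2). Eef1a1, a translation elongation factor, had 115 and 196 counts.

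Y-linked genes were found in both libraries, which the labels call male. Ddx3y had 6 and 9 counts, Eif2s3y 5 and 5, Uty 4 and 3 and Kdm5d 2 and 3. Xist, the RNA of the inactive X chromosome, had 0 counts in both, as had the Y-linked genes Sry and Zfy1. The 7 sex-linked genes summed to 17 and 20 counts. Of the 2 strain-linked genes, Nnt, which carries a deletion in some C57BL/6 substrains, had 1 and 4 counts, and H2-Ea-ps had 0 in both.

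Variable segments of the T cell receptor loci carried very few counts. The 34 annotated Trbv segments summed to 21 counts in replicate 1 and 43 in replicate 2, over 20 segments, of which 7 had counts in both libraries. Trbv3 held 3 of 21 counts in replicate 1 (14.3%, Clopper-Pearson 95% interval 3.05% to 36.3%) and 11 of 43 in replicate 2 (25.6%, 13.5% to 41.2%). Trbv15 held 4.76% (0.12% to 23.8%) and 20.9% (10% to 36%). Trbv12-2 had 4 counts and 0, and Trbv12-1 and Trbv5 each had 3 counts and 1. The 103 Trav segments summed to 6 and 12 counts, led by Trav14d-1 and Trav16 with 0 counts and 3 each. Traj segments summed to 3 and 1, Trdv segments to 0 and 6, and Trgv segments to 1 and 0. Segments of 1 family are similar in sequence, so single segments are uncertain. Of 35 segments compared between the libraries by a two-sided Fisher's exact test, added after the data were seen, 0 differed after Benjamini-Hochberg adjustment. The lowest was Trbv12-2 (exact p = 0.00942, adjusted p = 0.33), the 1 segment with an unadjusted p under 0.05. All 4 of its counts lay in replicate 1, so segments with 4 counts or fewer could hardly pass. The lack of calls therefore does not show equal usage.

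Transcript levels were weakly resolved. Among the genes of the 3 T lineage lists with a mean TPM of 5 or more, 44 had several transcripts and counts in both libraries. In 17 of these (38.6%, Clopper-Pearson 95% interval 24.4% to 54.5%) the same transcript was dominant in both libraries. For Cd4 that transcript held 62% and 72.8% of the gene's TPM, for Dntt 100% and 87.6%, and for Ets1 52% and 60%. For Tcf7 one transcript held 80% in replicate 1 and the other 71.4% in replicate 2. The dominant transcript held the lowest mean share in Satb1 (23.5%), Skap1 (24.7%), Ptprc (27%) and Arpp21 (27.3%), 4 genes with 10 or more annotated transcripts each, and it differed between the libraries in all 4.

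By class of feature, nuclear protein-coding genes held 43.6% ± 0.93 (SD, n = 2) of all TPM. These include the ribosomal protein genes, which held 2.72% ± 0.025 of all TPM. The mitochondrial rRNAs held 3.02% ± 1.28, and mitochondrial mRNAs and tRNAs 3.52% ± 1.87. Long noncoding RNAs held 3.73% ± 1.53 and pseudogenes 9.99% ± 2.95. The phiX174 row held 13% ± 3.51, and the 26248 rows named by a bare number 9.44% ± 1.81. The highest TPM values belonged largely to short or repeated features. Outside the mitochondrial and phiX174 rows, 9 of the 20 highest were shorter than 160 nt and 8 of the 20 had 0 counts in 1 library. Of the 20, 3 were rows named by a bare number, which carry no mouse gene identifier, and 3 were protein-coding genes of the annotation. Taken from a single library, the 20 highest shared 13 rows with these for either library, and 8 of the 20 were also among the 20 with the most counts. Gm42418, a noncoding RNA on chromosome 17 (39846958 to 39848788), had 719 and 1808 counts (16290 ± 9503 TPM). The elongation factor gene Eef1a1 (3864 ± 1990 TPM) and Lars2 (484 and 421 counts, 2754 ± 358 TPM) were among the 20. An identifier without a symbol in the reference, ENSMUSG00000045999, had the most counts of any gene, 2932 and 2205. Its posterior standard deviation (18.6 and 31.3) was near that of Gm42418 (18.6 and 30.9), so the division of reads between them is uncertain; together they held 8.83% and 8.51% of the mouse counts. Another, ENSMUSG00000082697, had 62.4 and 694.

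The libraries shared 6353 genes at a TPM of 1 or more, and 5927 of these were protein coding. A single count was worth a median TPM of 10.6 in replicate 1 and 10.4 in replicate 2, so this level admits almost any gene with a count. In replicate 1 alone 9276 genes reached that level, and in replicate 2 alone 9457. Only 383 genes had 10 or more counts in both. Across all 43346 mouse genes, log2(TPM + 1) correlated between the libraries with a Pearson r of 0.617 and a Spearman rho of 0.607; genes are not independent replicates, so no p-value is given. Over genes at a mean TPM of 1 or more, r was 0.034, and over the 668 genes with a mean count of 10 or more, a filter added after the data were seen, r was 0.391 and rho 0.55. An exact binomial test of the reads of each gene (edgeR, two-sided, Benjamini-Hochberg adjustment) compares these libraries only. It found 50 of 354 genes that differed beyond counting error, 23 higher and 27 lower in replicate 2. Of the 354, 55 belonged to a fixed list, and 18 of these were called, or 19 when adjusted over the list alone, here the members of all lists together. Called members with a higher share in replicate 2 included Mki67 (adjusted p = 2.76e-04), Trbc1, Trbc2 and Eef1a1, and called members with a lower share included Thy1, Tubb5, Rplp0, Tcf7 and Actb. Of the called list members, 8 were mitochondrial, of 10 tested. None of the 9 tested double-positive genes and neither of the 2 tested cortical genes was called, and no medullary gene passed the filter. Over all 354 genes 14.1% were called, so no call among so few genes does not show equal levels. The filter also left out Ly6d of the double-positive list. With a mean count of 10 or more, Ly6d was called, as 1 of 11 tested double-positive members, and 0 of 3 cortical members were.

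The scaling of the libraries moved the balance. Against the mouse totals, TMM scaling raised the log2 ratio of all genes (replicate 2 over replicate 1) by 0.098 and DESeq2 size factors raised it by 0.19, and the split of the calls became 26 higher and 22 lower with the latter. With the summed counts of each list, 0 of 28 lists differed between the libraries after Benjamini-Hochberg adjustment of the exact binomial test (lowest adjusted p = 0.0542), and 8 had an unadjusted p under 0.05. The double-positive list was 0.84 times as large a share in replicate 2 (exact 95% interval 0.746 to 0.946) and the macrophage and granulocyte list 0.438 times (0.234 to 0.792). These shares are of the mouse totals, and the widely expressed reference genes had a ratio near that of the double-positive list (0.873, 0.771 to 0.989). The fall is therefore not particular to double-positive genes. Some lists went the other way, such as immediate early and dissociation stress genes (1.44, 1.04 to 2.01). By the median log2 ratio of members, 2 of 27 lists lay outside the central 95% of matched random lists, regulatory T cell genes (median 3.87, percentile 98.5) and erythroid and platelet genes (median 3.84, percentile 98). The 6 and 5 measured members of these lists rested on 4 and 16 counts and on 3 and 8 counts. Of simulated lists of 15 genes without a shift, 5.5% fell outside that central range, so 2 of 27 lists is near that share. With a pseudocount of 0.1 the regulatory T cell list moved inside that range (percentile 96.2), and without a filter on mean TPM the erythroid and platelet list did (percentile 94.4). Both moved inside it with a mean TPM of 5 or more (percentiles 96.9 and 96.7), with TMM scaling (83 and 79.7) and with DESeq2 size factors (95.8 and 90).

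Mitochondrial genes moved apart between the libraries. Of 15 members, 11 were detected in both, and the list summed to 2510 and 2996 counts. The ribosomal RNAs mt-Rnr1 (341 and 843 counts) and mt-Rnr2 (795 and 1238) had larger shares in replicate 2, while the messenger RNAs mt-Cytb (168 and 72) and mt-Co1 (371 and 295) had smaller ones, each past the exact binomial test at an adjusted p of 0.00244 or lower. The messenger mt-Nd4 went the other way, with 100 and 137 counts, and did not pass that test (adjusted p = 0.273). Some reads were divided between mitochondrial genes and nuclear copies, which were paired by near-equal posterior standard deviations after the data were seen. mt-Co2 had 297 and 50.6 counts and Gm28661 0 and 116, together 297 and 167, a ratio of 0.493 (exact 95% interval 0.405 to 0.598). mt-Atp6 had 0 and 117 counts and Gm10925 245 and 0, together 245 and 117, a ratio of 0.417 (0.333 to 0.524). Single rows of such pairs are therefore uncertain.

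**Figure D3:**
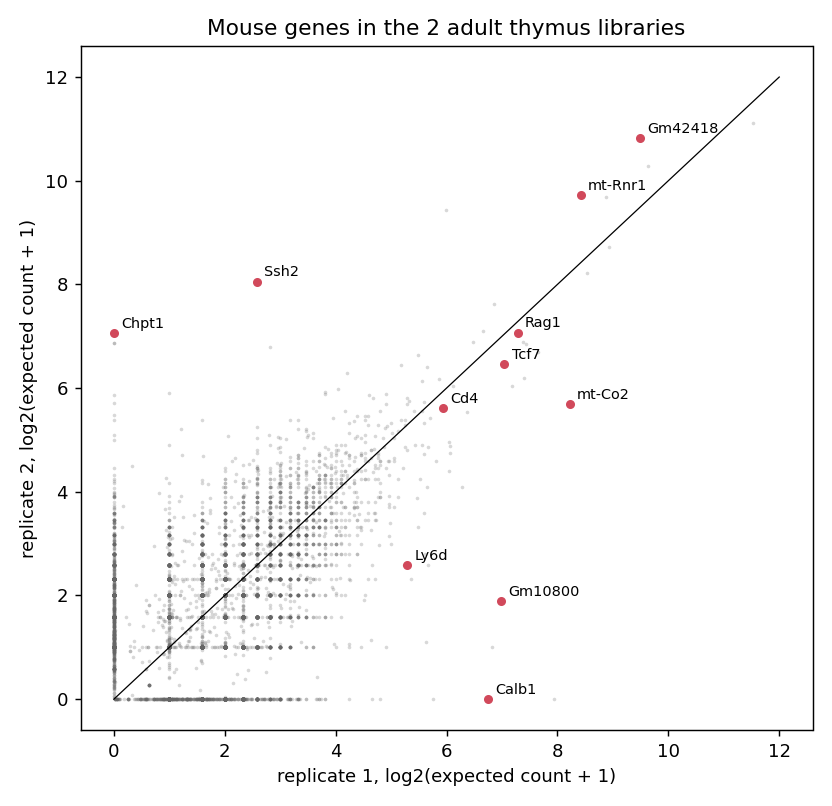
Log2 of the expected count plus 1 of each mouse gene with counts in replicate 1 (horizontal) and replicate 2 (vertical), with the line of equal counts. Red points are named genes. Rag1, Tcf7 and Cd4 lie near the line, while Ssh2 (5 and 264 counts), Chpt1 (0 and 132) and Calb1 (106 and 0) lie far from it.

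The common biological coefficient of variation between the libraries was 0.312 over the 354 genes kept by edgeR's filter. That filter asks for reads in both libraries and underestimated the spread on simulated data, recovering 0.286 where 0.4 was set. Over the 674 genes with a mean count of 10 or more, a filter added after the data were seen, the coefficient was 0.591 and the exact binomial test called 172 genes, 104 higher and 68 lower in replicate 2. The genes with the largest ratios lay in this wider set. Ssh2, a phosphatase of the actin regulator cofilin on chromosome 11 (77216287 to 77460220), had 5 and 264 counts. Chpt1, an enzyme of phosphatidylcholine synthesis on chromosome 10 (88452745 to 88504073), had 0 and 132 counts, all on 1 of 9 transcripts. With the floor of 3 counts in place of 0, it was 38.7-fold higher in replicate 2. This fold leaves out the counting error of the 132 counts and is no lower bound. Calb1, a calcium-binding protein on chromosome 4 (15881264 to 15908064), had 106 and 0 counts, all on 1 of 3 transcripts. It was 40.3-fold lower in replicate 2 by the same reckoning. Ly6d of the double-positive list had 38 and 5 counts. The adjusted p of these 4 genes was 8.25e-07 or lower (edgeR exact binomial test).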

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

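The tests of phiX174 were chosen after its counts had been seen. Counts of phiX174 and of the numbered rows lie outside the mouse genes that the comparisons use, and were noted because they exceeded the 3 counts that a count of 0 allows.

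The phiX174 row held 34766 expected counts in replicate 1 and 24714 in replicate 2, or 45.6% and 34.3% of all counts. The tables argue against an ERCC mix that also carried phiX174, since the 96 ERCC rows summed to 0 counts over both libraries. Without that row the median log2 ratio of 12351 genes moved by -0.071, from -0.05 to -0.12. Leaving out a row rescales all TPM of a library by the same factor, so this shift follows from the phiX174 shares themselves and decides nothing about the comparison of single genes. How phiX174, a genome often added to sequencing runs as a control, came to be counted was not tested, and no biological explanation was tested.

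The rows named by a bare number summed to 170.83 expected counts in replicate 1 and 142.9 in replicate 2, yet held 10.7% and 8.16% of the TPM.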

How the results depend on the processing

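The filter on a mean count of 10 or more, the ranking by expected count and the ratios of summed counts were chosen after the data were seen. The posterior mean TPM changed most values. It gave 33445 detected genes against 6353, a correlation of 0.974 against 0.617, and 360 of 455 list genes detected against 225. It also kept 11 of the 20 rows of highest TPM, a set with 3 numbered rows that carry no mouse gene identifier. It gave list medians of 14.2 TPM (T cell receptor complex), 12.2 (T lineage factors), 14 (double-positive) and 3.65 (cortical), and the same dominant transcript in 55.6% of genes against 38.6%. By construction it adds a prior amount to rows without reads, and 72.8% of that unit lay on numbered rows in replicate 1. Rescaled TPM raised the medians of the first 2 lists to 279 and 125. With 10 counts in place of a TPM of 1, 383 genes were detected in both libraries. The correlation was 0.676 on counts per library total and 0.034 over genes at a mean TPM of 1 or more, where a filter on the mean leaves out genes low in both libraries. The coefficient of variation, 0.312, was 0.515 with no filter, 1.21 at a mean count of 50 or more and 0.591 at 10 or more. From DESeq2 it was 0.283, the root of the mean of the dispersions of single genes. The root of their median was 1e-04, so 0.283 does not describe a typical gene. The exact binomial test called 128 genes with no filter (72 higher, 56 lower), 29 of 36 at a mean count of 50 or more (14 higher, 15 lower) and 172 at 10 or more (104 higher, 68 lower), against 50. These filters test other genes, and apart from that the cause was not tested. Of these 20 rows, 8 were kept when ranked by count and 13 with either library alone. 1 list in place of 2 lay outside the central 95% of random lists with a pseudocount of 0.1 and with a mean TPM of 5 or more; 0 lists passed the exact binomial test on summed counts, with or without the most abundant rows. The regulatory T cell list fell inside that central range at a median log2 ratio of 6.54 (pseudocount 0.1), 4.52 (TMM), 4.56 (DESeq2) and 4.31 (mean TPM of 5 or more), and the erythroid and platelet list at 4.52 (TMM), 4.56 (DESeq2), 3.84 (no filter) and 3.84 (mean TPM of 5 or more); the cause was not tested. With single libraries the list medians ranged from 176 to 205 TPM (T cell receptor complex), 71.7 to 96.1 (T lineage factors), 174 to 291 (double-positive) and 0 to 6.51 (medullary). Both single-library medians of the T cell receptor complex and of the T lineage factors lay below the median of the means, 221 and 96.7. Over all 30 lists, the median moved by more than its SD in 24 with the posterior mean, 19 with rescaled TPM, 19 without replicate 1 and 16 without replicate 2. Lists that were inside the central range moved outside it with TMM (2), DESeq2 (2), no filter (1) and a mean TPM of 5 or more (1). Of 166 named genes, 135 moved by more than their SD with the posterior mean, and of 160 with rescaled TPM, 51 did. For the counts of genes and lists, the segment share and the class share, the remaining alternatives stayed within 1.5 times for counts and within the SD or interval for values. For the class share with each library alone this was fixed in advance, since each of 2 values lies within the SD of their mean. No paired analysis was possible because the series holds 1 group. Depth limits single genes: at 10 counts the exact Poisson interval spans several-fold, and members at 1 count cannot be ranked.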

Other observations

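Among genes outside the lists, Srrm2, a splicing factor of nuclear speckles, had 68.7 and 65 counts. Replication-dependent histone genes, whose messages lack poly(A) tails, summed to 44 and 28 counts over 64 genes, 0.106% and 0.059% of the mouse counts. Ribosomal protein genes held 1.64% and 1.54% of the mouse counts.

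Of the tests below, those of reads shared by Gm42418 and of ribosomal RNA alone, and all intervals over genes, were chosen after the result had been seen. Gm42418, mt-Rnr1, mt-Rnr2, Rn7sk, Malat1 and the annotated snRNAs and snoRNAs were pooled because they were seen to be higher. These rows of ribosomal and other RNA that is not messenger RNA held 5.77% of the mouse counts in replicate 1 and 10.4% in replicate 2. The ratio was 1.8 (1.42 to 2.26 over genes). The noncoding RNA Gm26917 had 76.7 and 16 counts, a ratio of 0.182 (exact 95% interval 0.099 to 0.315). Whether its reads were divided with those of Gm42418 was not tested, so its fall does not count against the pattern. With ENSMUSG00000045999 added, the pool held 12.9% and 15%, a ratio of 1.17 (0.763 to 2.2 over genes), and a candidate explanation for the rise of Gm42418 is a division of reads between these 2 rows, whose sum had a ratio of 0.963 (exact 95% interval 0.921 to 1.008). The posterior standard deviation of Gm42418, 3.13% of the difference between the libraries, does not exclude this, since that of mt-Atp6 in replicate 2 was only 6.66% although its reads appear divided with Gm10925. A carry-over of ribosomal RNA alone stays open, since the rows outside ribosomal RNA, with a ratio of 1.654, were picked for being higher, and snRNAs at 2.34 (0.748 to 6.27 over genes) and snoRNAs at 1.69 (0.51 to 4.4) had intervals that include 1. A general carry-over of RNA without poly(A) tails, with histone genes at 0.558 (counting interval 0.335 to 0.916, but 0.285 to 1.21 over genes), and more cycling thymocytes, with the proliferation list at 1.069 (counting interval 0.894 to 1.28, below that of the pattern, but 0.639 to 1.62 over genes, and 1.35 without Tubb5) and members that went both ways, stay open too, as does a difference between the animals, which was not tested.

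The spread between the libraries was far above counting error. Of 668 genes with a mean count of 10 or more before rounding, 15 had 0 counts in 1 library, where counting error alone would give 0.000205. Among them were Chpt1, Calb1, Stx4a (0 and 57 counts), Galnt13 (53 and 0), Thg1l (0 and 51.5) and Exoc8 (0 and 31). Their posterior standard deviation in the library with counts was at most 0.82. Others of the 15, such as Gm10925, Gm28661 and mt-Atp6, had high ones (59.9, 29.8 and 7.76), so their 0 counts are uncertain. Leaving out genes with a posterior standard deviation of 1 or more kept 87.4% of the coefficient of variation (0.516 against 0.591). This argues against shared reads as the main source only where the sharing raises that standard deviation. Shared reads that leave it small stay open. Repeated reading of molecules stays open: the median index of dispersion was 0.799 against 0.383 from counting error in genes with a summed count of 5 to 9, and this excess was 8.43% of that of genes with 50 or more, but under any constant coefficient of variation the excess grows with the count. Read positions, which could show repeated reads, are not in the tables, and no biological explanation was tested.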
